A study of Mus musculus with 6 samples.

How the data were processed

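RNA sequencing counts were available for 6 libraries of heart ventricle from mouse embryos of embryonic day 17.5 on an NMRI background. Per the labels, 3 libraries came from controls with a wild-type genotype label and 3 from embryos labelled as conditional nulls, which carry a tamoxifen-inducible Cre under the VE-cadherin promoter and floxed Prox1 alleles. Per the labels' protocols, pregnant females received tamoxifen at 5 mg per 40 g of body weight at embryonic days 13.5 and 14.5, and total RNA was extracted from dissected ventricles with a column kit.

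The values deposited by the authors are whole-number counts per gene, 1 file per library, with no normalisation. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 were used with genome build mm10; the role and order of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Each file listed 25006 Ensembl gene identifiers. Of these, 24991 were matched to GENCODE M21, an annotation of the same build, for symbols and coordinates, and 15 were not; the unmatched identifiers held at most 0.00212% of a library's counts. No file held a line for unassigned reads. All 13 mitochondrial genes stood at 0 in every library, so the mitochondrial share, often read as a sign of RNA quality, could not be measured.

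Total counts ranged from 35195544 to 44330594 per library. At this depth 3 counts equal 0.0677 to 0.0852 CPM, the counts scaled to library size, and genes below this level could not be measured. Intervals computed from counts cover counting error only, because reads without molecular identifiers are not independent molecules.

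Computation from the deposited counts used R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled with the trimmed mean of M values (TMM), and null-labelled libraries were compared with controls by the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another is named. Standard errors of log2 fold changes were obtained from the fold change and the F statistic. Normalised expression is given in TMM-scaled CPM as mean ± SD with n = 3 per group.

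Before the data were examined, 35 gene lists were fixed, covering cell types, signalling pathways, stress responses and markers of neighbouring tissues. Of these, 32 had at least 3 tested genes and were compared with all other genes by camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. For each list the number of changed genes was counted over all genes and also adjusted over the list alone. Shares of counts per library were compared by exact two-sided permutation tests, whose smallest p with 3 libraries against 3 is 0.1.

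Genes named in the text were fixed by a rule before the data were examined. It always names Prox1, Reln, Lyve1, Flt4, Pdpn, Ccl21a, Pecam1, Cdh5, Vldlr, Mki67, Nppa and Myh7, and another gene that is not reported here. It adds the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 1 CPM in the higher group and no overlap between the groups, leaving out predicted and sex-linked genes, and up to 4 genes of smallest p per list. Other genes named were chosen after their values were seen.

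The test was tried on simulated counts drawn from the real means, library sizes and dispersions for 14815 genes, of which 14704 passed the filter, with 50 genes changed at each fold. It recovered 20% of genes changed 1.2-fold, 78% of those changed 1.5-fold, 96% of those changed 2-fold and 96% of those changed 3-fold, with 6 false calls. The genes changed at each fold were picked from those with a mean of at least 1 CPM, so the recovery does not cover lower genes. With no gene changed the gene test made 4 calls, and the list test made 0. With 2 lists changed the list test called both and 1 other. Genes were simulated independently of each other, so these list results do not show how the list test behaves with correlated genes. The search for clusters of calls found a window in 1 of 100 random placements of calls.

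Alternatives were other scalings, other filters, DESeq2 1.42.0 and limma-voom in place of edgeR, each library left out in turn, a term for replicate number, a term for sex, removal of haemoglobin genes, and a threshold of 0.1. After the data were seen, male libraries alone, the omission of 2 null-labelled libraries and the omission of a chromosome 4 segment were added. Genes that share reads with close copies were kept, and those recognised as such are named as uncertain.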

Results

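Heart ventricles of mouse embryos at embryonic day 17.5 were profiled by RNA sequencing in 3 control libraries and 3 libraries labelled as Prox1 conditional null. Prox1 is the transcription factor that sets and keeps lymphatic endothelial identity, and the series asked which pathways in the developing heart depend on cardiac lymphatic vessels. In the null design, tamoxifen activates a Cre recombinase expressed in endothelial cells. Control libraries held 44330594, 35868181 and 35195544 counts and null-labelled libraries 40331507, 36216206 and 41408973, with 17751 to 17960 genes detected. The labels do not say whether the libraries came from separate embryos, and the p-values measure the spread between these samples. By Y-linked genes and Xist each group held 2 libraries called male and 1 called female, though null 1 and null 3 carried Xist as well and may be mixed samples; the libraries of a group are therefore not all repeats of 1 sample, but part of the spread may be technical.

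The targeted gene was not lower in the null-labelled libraries. Prox1 (chromosome 1, 190118035 to 190170714, GRCm38) had 147 ± 3.16 CPM in controls and 164 ± 3.91 CPM in null-labelled libraries (SD, n = 3), a log2 fold change of 0.15 ± 0.03 (SE) with adjusted p = 0.0331. Its counts were 6549, 5164 and 5265 in controls and 6581, 5809 and 6924 in null-labelled libraries. Cardiomyocytes also express Prox1, and counts over the whole gene include exons outside a deleted part, which the labels do not name, so Prox1 does not settle the labels. Counts of Esr1, part of which inducible Cre fusions carry, were 244 to 298 in null-labelled libraries and 9 to 19 in controls, which goes with the Cre labels but does not show that Prox1 was deleted. The groups are therefore called control and null-labelled, and every direction rests on the labels. Cre was named for 3 null-labelled and 0 control libraries, so no change between groups can be assigned to Prox1 loss rather than Cre. The Prox1 call ended when control 1, control 2 or any null-labelled library was left out, with adjusted p from 0.0646 to 0.13, and with a sex term (adjusted p = 0.0568).

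Among lymphatic endothelial genes, Reln, which encodes the secreted protein reelin, was 1.65-fold lower in null-labelled ventricles (26.5 ± 0.701 against 16.1 ± 1.16 CPM, log2 fold change −0.72 ± 0.07, adjusted p = 0.000654). Mmrn1, a lymphatic marker, was 5.2-fold lower (log2 fold change −2.38 ± 0.36, adjusted p = 0.0211) and Sox18, a transcription factor upstream of Prox1, was 1.41-fold lower (adjusted p = 0.0029). Other markers did not pass: log2 fold changes were −0.11 for Lyve1, −0.05 for Flt4 and −0.05 for Pdpn, with adjusted p of 0.748, 0.705 and 0.797. Macrophages also express Lyve1 and epicardium Pdpn, so their levels in whole ventricle do not report on lymphatic cells alone. Of 13 tested lymphatic genes, 3 fell, 1 (Prox1) rose and 9 did not pass; adjusted over the list alone, 5 changed. The list was called lower (adjusted p = 0.000387), but not with an estimated correlation (adjusted p = 0.6 with an estimated correlation). Its median log2 fold change was −0.0513, and 7 of the 10 splits of the libraries, the real one included, gave a median at least as large in size. Ccl21a had 0 counts in all 6 libraries; it has near copies, whose shared reads the counting may drop, so its level is uncertain. The Mmrn1 call was lost without control 2 (adjusted p = 0.0623), null 2 (0.0764) or null 3 (0.0897). Of 11 genes of the reelin pathway, 1 fell, Reln itself, and 1 changed adjusted over the list alone; the list was not called by camera (adjusted p = 0.165) and was called lower by fry (adjusted p = 0.0362), although 6 of its 11 genes lay above 0 and its median was 0.00347. The receptor gene Vldlr had a log2 fold change of 0.01 (adjusted p = 0.895).

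**Figure D1:**
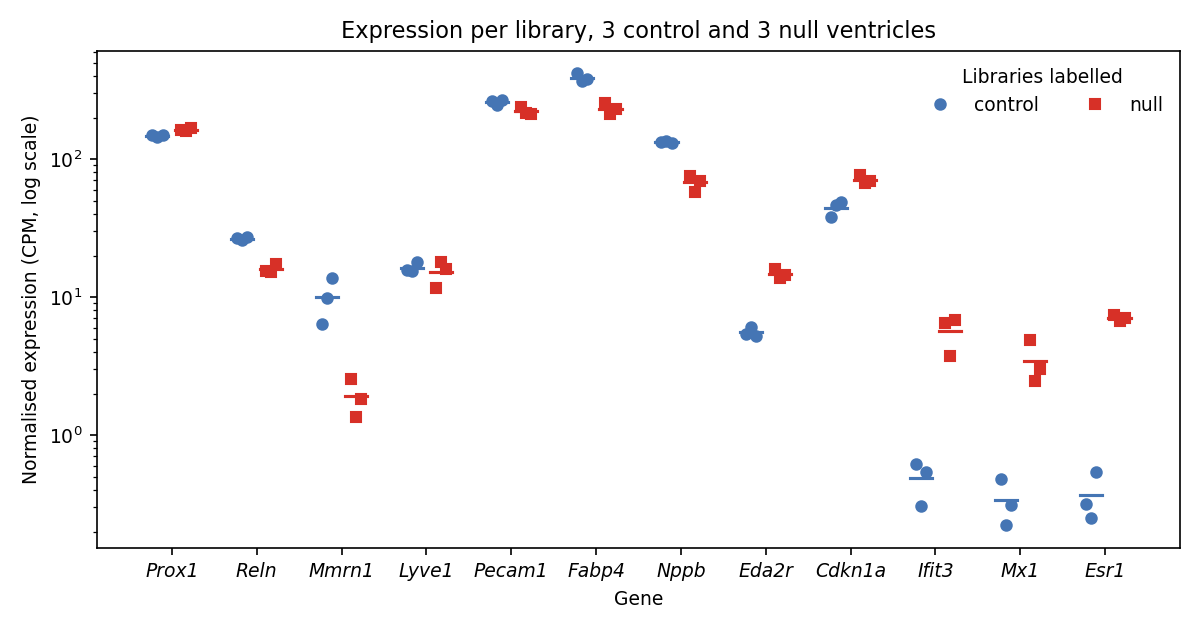
Normalised expression in CPM (log axis) of 12 genes in each of 3 control and 3 null-labelled libraries; each point is a library and each bar a group mean. Reln had 26.5 CPM in controls and 16.1 CPM in null-labelled libraries, while Prox1 had 147 and 164 CPM.

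Across the 14815 genes tested, 801 changed, 360 higher and 441 lower in null-labelled ventricles. The changes were mostly small: the median size among changed genes was 0.36 on the log2 scale, 75 genes were more than 2-fold higher and 24 more than 2-fold lower. All 801 had no overlap between groups; among all tested genes 26.6% had none, where 10% is given by chance. The count fell to 402 without control 2, 385 without null 1, 258 without null 2 and 277 without null 3. Null 1 and null 3 carried Y-linked counts at 92.5% and 97.2% of the control male level together with Xist at 3.2% and 9.95% of the female level, and without both libraries 52 genes changed.

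Genes induced by interferon rose together. Ifit1, an antiviral effector, was 18.8-fold higher (0.624 ± 0.118 against 11.7 ± 4.37 CPM, log2 fold change 4.23 ± 0.37), Mx1 was 10.02-fold higher (log2 fold change 3.32 ± 0.35) and Usp18, a regulator of interferon signalling, 8.96-fold higher (log2 fold change 3.16 ± 0.33). All 16 interferon genes tested rose, and 16 changed adjusted over the list alone, with a median log2 fold change of 2.33. The list was called higher (adjusted p = 8.01e-55), with adjusted p = 0.135 with an estimated correlation. Outside the list, by size of change, Ifit3b (log2 fold change 3.80), Nlrc5 (2.98) and Oasl1 (2.91) also rose, and Ifit3 within it (3.52). Ifit3 and Ifit3b are near copies whose reads the counting could divide, so their values are uncertain. Cxcl10, a chemokine, rose by a log2 fold change of 4.35, from 11 counts summed over controls to 239, a ratio of 21.3 (95% counting interval 11.7 to 43.2). The number of interferon genes past the threshold was 9 without control 2, 7 without control 3, 6 without null 3 and 2 without null 1 and null 3, while the list median in these fits was 2.16, 2.25, 2.35 and 1.89. Macrophage markers rose with this group: of 14 genes, 5 rose and 9 did not pass, and 11 changed adjusted over the list alone. C1qa, a complement gene, had a log2 fold change of 0.72 ± 0.15 and Cx3cr1 of 0.51 ± 0.12. The macrophage list was called higher (adjusted p = 1.28e-08; adjusted p = 0.378 with an estimated correlation). In edgeR 0 macrophage genes passed without control 2, without null 1 or without null 2, against 5 with all libraries. The list median was 0.428, 0.354 and 0.435 in these fits and 0.459 with all libraries. Without control 1 the number past the threshold was 1, without null 3 it was 4 and without control 3 it was 7. With all libraries 11 had an unadjusted p under 0.05, and DESeq2 called 8 and limma-voom 5.

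Targets of p53, the DNA damage response factor, also rose. Eda2r, a receptor of the tumour necrosis factor family, was 2.64-fold higher (5.58 ± 0.417 against 14.8 ± 1.12 CPM, log2 fold change 1.40 ± 0.09, adjusted p = 0.000103). Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.67 ± 0.09, Trp53inp1 of 0.69 ± 0.05 and Sesn2 of 0.49 ± 0.07. Of 20 genes, 9 rose, 0 fell and 11 did not pass; adjusted over the list alone 12 rose and 1 fell. The list was called higher (adjusted p = 2.43e-11), with adjusted p = 0.084 with an estimated correlation. The number of p53 targets past the threshold was 5 without null 1, 4 without null 2, 5 without null 3 and 2 without null 1 and null 3, while the list median in these fits was 0.181, 0.215, 0.21 and 0.175, against 0.2 with all libraries.

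Endothelial genes were lower. Fabp4, a lipid chaperone of capillary endothelium, was 1.68-fold lower (389 ± 26.6 against 232 ± 20.4 CPM, log2 fold change −0.75 ± 0.07, adjusted p = 0.00175). Sox17, an arterial transcription factor, was 2.01-fold lower, and Egfl7 and Tie1 were 1.29-fold and 1.17-fold lower. Pecam1, a junction protein, had a log2 fold change of −0.22 ± 0.05 (adjusted p = 0.0487), while Cdh5, which encodes VE-cadherin, had −0.12 and did not pass (adjusted p = 0.298). Of 20 genes 10 fell, 1 rose (Mmrn2, log2 fold change 0.31) and 9 did not pass; adjusted over the list alone 14 fell and 1 rose. The list was called lower (adjusted p = 3.17e-14; adjusted p = 0.378 with an estimated correlation). The Pecam1 call was lost in 12 of 19 alternatives, and the number of lower genes was 3 without null 2, 3 without null 3 and 1 without null 1 and null 3, while the list median in these fits was −0.203, −0.189 and −0.252, against −0.224 with all libraries. Of 8 endocardial genes 0 changed in edgeR, DESeq2 or limma-voom, 0 changed adjusted over the list alone, and 2 had an unadjusted p under 0.05.

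**Figure D2:**
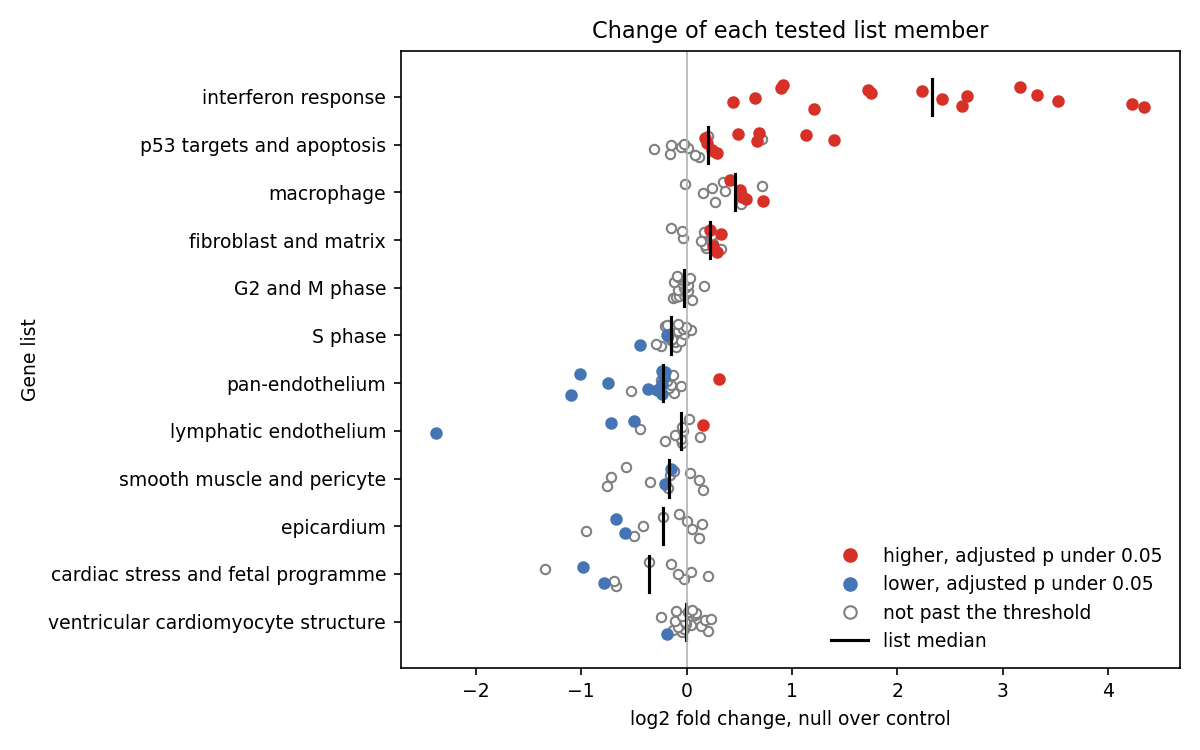
Log2 fold change, null-labelled over control, of each tested gene in 12 of the 32 tested lists, chosen after their values were seen; filled points passed an adjusted p under 0.05 and vertical bars are list medians. All 16 interferon genes lie above 0, and 10 of 20 endothelial genes passed below 0.

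Markers of cardiac load fell in part. Nppb, which encodes the natriuretic peptide BNP, was 1.97-fold lower (134 ± 2.59 against 67.7 ± 9.24 CPM, adjusted p = 0.00424) and Ankrd1, a stretch-responsive gene, 1.72-fold lower (adjusted p = 0.00815). Nppa, the atrial natriuretic peptide gene, had a log2 fold change of −1.35 ± 0.32 and did not pass (adjusted p = 0.107), though it passed in 3 of 18 alternatives. Of 11 genes 2 fell in edgeR and 9 did not pass, and 5 fell adjusted over the list alone. DESeq2 called 4 lower and limma-voom 3. The list was called lower by camera (adjusted p = 1.61e-07, and adjusted p = 0.185 with an estimated correlation). In edgeR the number of lower genes was 3 without control 1 or null 2 and 4 without null 1. The list median ranged from −0.56 without control 1 to −0.19 without control 3. Of 20 sarcomere and calcium-handling genes, 1 fell in edgeR, Actc1 (log2 fold change −0.18), and 3 changed adjusted over the list alone. In edgeR 8 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 1. Actc1 lost its call without each library but control 3 (adjusted p from 0.0637 to 0.148); Myh7 had a log2 fold change of 0.04 (adjusted p = 0.647). Nppb (chromosome 4, 147985788 to 147987205) and Nppa lie in a segment where 21 of 65 tested genes changed (32.3%, against 5.29% elsewhere). These genes span 145585166 to 150946102, and the segment was set to whole megabases around them after the calls were seen. Without the segment the median of the cardiac load list was −0.15 in place of −0.35 (camera adjusted p = 0.00242). Of the 9 genes then left, 1 was called lower, Ankrd1. Ccn2, also outside the segment, had a log2 fold change of −0.69 and did not pass (adjusted p = 0.0599). In the whole list 9 genes lay below 0 and 2 above. The list was not tested without Ankrd1.

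**Figure D3:**
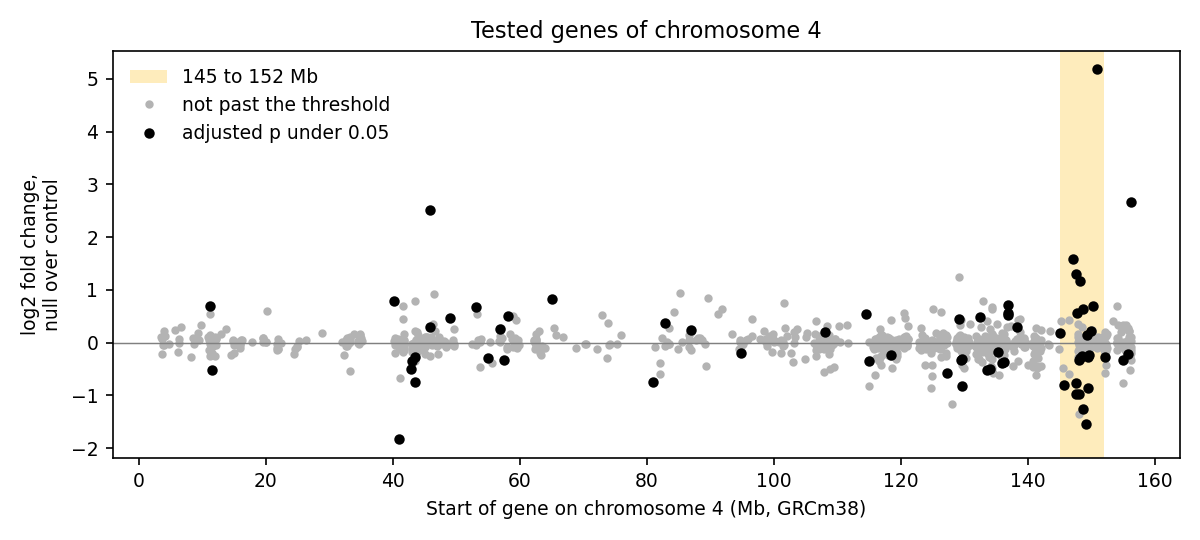
Log2 fold change, null-labelled over control, of tested genes along chromosome 4 (Mb, GRCm38); black points passed an adjusted p under 0.05 and the shaded band marks the segment. In the band 9 genes were higher and 12 lower.

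Among changed genes with a mean of at least 1 CPM in the higher group, no overlap between groups and neither predicted nor sex-linked, the largest rise was in Tnfrsf9, a T cell costimulatory receptor in the same chromosome 4 segment, which had 5 counts summed over controls and 200 over null-labelled libraries, a ratio of 39.1 (95% counting interval 16.5 to 122). Esr1, the oestrogen receptor gene, rose 19.1-fold, from 14, 9 and 19 counts to 298, 244 and 290 (adjusted p = 2.57e-05); the inducible Cre is a fusion to a ligand-binding part of this receptor, and gene counts cannot tell transgene reads from those of Esr1. Among such genes the largest fall was in Maats1 (19.2-fold lower, log2 fold change −4.26 ± 0.27), a cilia gene. It was followed by Serpind1 (−2.87), the thrombin inhibitor heparin cofactor, Mmrn1, Rtn4r (−2.16), a receptor of myelin inhibitors, and the keratin Krt14 (−1.91). Aqp7 (−1.83), Dcdc2a (−1.66), Dmkn (−1.59), Anxa8 (−1.53) and Masp2 (−1.26), which lies in the chromosome 4 segment, completed the 10 largest falls; Tc2n (−4.00) and Cort (−1.54) also fell but stayed under 1 CPM. The calls of Krt14, Aqp7, Dcdc2a, Dmkn, Anxa8, Masp2 and Cxcl10 were each lost when some single library was left out (adjusted p from 0.0539 to 0.119).

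Cell cycle genes moved little. Of 20 S phase genes 2 fell, Cdc6 (log2 fold change −0.44 ± 0.08), which licenses replication, and Mcm6 (−0.19 ± 0.04), and 9 changed adjusted over the list alone; the list was called lower (adjusted p = 9.01e-05; adjusted p = 0.6 with an estimated correlation). In edgeR the number of lower S phase genes was 8 without control 3, 0 without null 2 and 1 without any other library, and Mcm6 lost its call without each library but control 3 (adjusted p from 0.11 to 0.148); with all libraries 9 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 1. Of 20 G2 and M phase genes 0 changed in edgeR, DESeq2 or limma-voom and 0 changed adjusted over the list alone, while 3 had an unadjusted p under 0.05; Mki67, a proliferation marker, had a log2 fold change of −0.12 (adjusted p = 0.184). Fibroblast genes rose in part: of 18 genes 4 rose, Pdgfra, Tcf21, Col1a1 and Col6a1, by log2 fold changes of 0.33, 0.22, 0.29 and 0.25, and adjusted over the list alone 7 rose and 1 fell (Vim). The fibroblast list was called higher (adjusted p = 2.17e-05; adjusted p = 0.6 with an estimated correlation). In edgeR the number of higher fibroblast genes was 9 without control 3, 2 without control 1, 1 without control 2, null 1 or null 3 and 0 without null 2, and Col1a1 lost its call without each library but control 3 (adjusted p from 0.0571 to 0.098); with all libraries 10 had an unadjusted p under 0.05, and DESeq2 called 7 and limma-voom 4. Of 11 epicardial genes 2 fell, Krt19 and Upk1b (log2 fold changes −0.59 and −0.67), and of 12 mural genes 2 fell, Cspg4 and Smtn (−0.21 and −0.15). In edgeR 0 epicardial genes were lower without control 1, null 2 or null 3 and 0 mural genes without null 1, null 2 or null 3; with all libraries 4 and 7 had an unadjusted p under 0.05, and DESeq2 called 3 and 2 and limma-voom 2 and 1. In each of these lists 3 changed adjusted over the list alone, and each was called lower with adjusted p of 0.0331 and 0.0304, or adjusted p = 0.6 with an estimated correlation. Of 10 erythroid genes 0 passed in edgeR, 0 in limma-voom and 2 in DESeq2, 0 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05, though the list was called lower (adjusted p = 0.0136; adjusted p = 0.6 with an estimated correlation); haemoglobin genes, whose near copies share reads so that these shares are uncertain, took 0.309 ± 0.162% of counts in controls and 0.157 ± 0.0384% in null-labelled libraries (exact permutation p = 0.3). Control 3 had the highest haemoglobin share (0.484%) and 322 counts of the liver gene Alb, against 3 and 12 in the other controls and 20 to 125 in null-labelled libraries. The epicardial list was not called without control 1, control 3, null 2 or null 3, the mural list without control 3, null 2 or null 3, and the erythroid list without control 3, null 3 or the haemoglobin genes (adjusted p = 0.093). The epicardial list was also lost with limma-voom (adjusted p = 0.116), and the epicardial and mural lists in male libraries only (adjusted p of 0.453 and 0.428).

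In all, 11 of 32 lists were called, 4 higher and 7 lower, and 0 were called with an estimated correlation. Fry called 6, of which 4 were among the 11 and the others were the reelin pathway and heat shock lists. The other 9 splits of the 6 libraries gave 9 to 13 called lists, and for the fibroblast, S phase, epicardial, mural and erythroid lists some other split gave as low a camera p; for the other 6 of the 11 none did. A list call at the preset correlation therefore did not by itself separate the real grouping from the others.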

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

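The alternatives other than male libraries only, the omission of null 1 and null 3 and the omission of the chromosome 4 segment were chosen before the data were examined. With each library left out in turn, changed genes numbered 258 to 942, higher genes 127 to 448 and lower genes 126 to 494; fewer samples account for part of this. DESeq2 called 541 genes higher, and an adjusted p under 0.1 gave 1430 changed genes, 679 higher and 751 lower. Male libraries only, which keep null 1 and null 3 despite their Xist counts, gave 461 changed and 218 lower, and the fit without null 1 and null 3, which leaves 1 null-labelled library assumed to vary like the controls, gave 52, 21 and 31. Lists called numbered 0 with an estimated correlation and 6 with fry.

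The log2 fold change of Prox1 ranged from 0.13 to 0.17 with each library left out. It did not pass with the replicate block (0.154), a sex term (0.154), male libraries only (0.18) or without null 1 and null 3 (0.12); the cause was not tested. Replicate numbers did not pair the samples, with correlations of same-numbered libraries of −0.0643, −0.0467 and −0.121; the replicate block gave 570 changed genes, 487 of them among the 801. Some genes not past the threshold changed sign: with each library left out, Lyve1 ranged from −0.242 to 0.0487, Pdpn from −0.101 to 0.00804 and Vldlr from −0.00856 to 0.0349, and Lyve1 was 0.129 without null 1 and null 3 and Pdpn 0.0633 in male libraries only; the cause was not tested. Of 62 changed genes followed, 16 passed in every alternative that tested them and 36 were lost without some library.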

Other observations

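The tests on macrophage number, 1 unusual library, Cre, shared reads, copy number, an inherited segment and the spread among endothelial genes were chosen after the results were seen. For the capillary, arterial, SRF and YAP, further p53 and antigen presentation lists, the requirement that no other split of the libraries reach as low a camera p was set after the first p-values were seen.

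Genes of growth factor signalling changed singly. Igfbp5 and Igfbp3, which bind insulin-like growth factors, rose by log2 fold changes of 0.38 ± 0.06 and 0.61 ± 0.11 and Igfbp6 fell by 0.93, while Igf1 and Igf2 had 0.04 and 0.02 and did not pass. Of 14 genes of this axis 3 changed in edgeR, and 6 changed adjusted over the list alone. DESeq2 called 5 and limma-voom 3, and edgeR called 1 without control 2 or null 2 and 2 without null 1. The list was not called by camera (adjusted p = 0.0752). Angpt1, a ligand of the Tie2 receptor, rose by 0.53 ± 0.08 and Vegfd, a lymphangiogenic factor, by 0.61 ± 0.15, while Pdgfb, which recruits pericytes, fell by 0.33; of 17 such factors 3 changed, and 6 changed adjusted over the list alone. Vegfd and Igfbp3 each lost their call without any library but control 3 (adjusted p from 0.113 to 0.141 and from 0.0526 to 0.126), and Igfbp6 lost its call without control 2, null 2 or null 3 and Pdgfb without null 2 or null 3.

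Energy metabolism showed few changes. Of 22 fatty acid oxidation genes 0 changed in edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, and of 24 nuclear oxidative phosphorylation genes 1 rose, Ndufa1 (log2 fold change 0.20); adjusted over the list alone these were 0 and 1. In edgeR 0 oxidative phosphorylation genes changed without control 2, null 1 or null 2; with all libraries 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1. Eno1 rose by 0.69 and Gapdh fell by 0.50, but both have near copies that can take their reads, so these values are uncertain; Gapdh lost its call without each library but control 2 (adjusted p from 0.0546 to 0.0856), and Eno1 lies in the chromosome 4 segment.

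For the rise of interferon genes, more macrophages, 1 unusual library and Cre activity were weighed. Of 16 genes, 14 rose by more than the largest rise among macrophage markers (0.72), which argues against macrophage number alone. Over these 16 genes the mean log2 CPM of the lowest null-labelled library lay 1.48 above that of the highest control, with an SD between libraries of at most 0.364, which argues against 1 library as the whole cause. With each null-labelled library left out in turn the list median was 2.11, 2.51 and 2.35, the lowest with a 95% bootstrap interval over genes of 1.08 to 2.99. The comparison of library means replaced earlier tests after their values were seen. A test on this interval left 1 library open as the cause, and a looser bound was tried and dropped. A count of genes without overlap was dropped because the calls had fixed its outcome. The interval measures scatter between genes, not between libraries. The label names Cre in 0 control and 3 null-labelled libraries, so Cre recombinase activity and loss of Prox1 cannot be told apart. This holds for every other change between the groups too, the p53 targets included. Antigen presentation genes, with Psmb8 higher by 1.79 and Psmb9 by 1.48, had a camera p of 8.07e-08, and all 10 lay above 0. Further p53 targets had a camera p of 0.01002, with 14 genes above 0 and 8 below. The real split had the largest median for the first list (0.42, with 0.33 in size the highest of the others) and the second (0.117, with 0.0672). Another split reached as low a p for the first list, which stays open, and none for the second. The second moved in the direction predicted for a p53 response, though 2 of its 22 genes rose (Dcxr and Foxo3) and 1 fell (Kitl). With 10 splits, the lowest p falls to the real split by chance at a share of 0.1, so a p53 response stays open too. With an estimated correlation both lists had an adjusted p of 0.0886.

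Calls clustered in the chromosome 4 segment, where the 1 window past the threshold among 529 windows of 5 Mb lay (adjusted p = 5.11e-09). Shared reads among zinc-finger and predicted gene copies are a candidate explanation. Without these genes 14 of 53 genes still changed, so they were not the only genes called, though the 14 include Eno1, which has near copies. The one-sided Fisher exact p of 9.48e-07 cannot decide the question, because the segment was set around the calls and the p is not corrected for that. Gain or loss of a copy would move the genes together, whereas their median log2 fold change was −0.00199 (95% bootstrap interval −0.10 to 0.07). An inherited haplotype linked to the transgene or another inherited segment may account for the cluster; a single window fits it, but without genotypes it cannot be told apart from a response of these genes.

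The fall of endothelial genes may reflect fewer endothelial cells or a change in vessel type. The 20 genes differed from each other by more than their errors, with log2 fold changes from −1.09 to 0.31 (chi-square test of heterogeneity, p = 6.91e-45). The test takes errors estimated from 6 libraries as exact and the genes as independent, so the size of this p is not reliable. The spread argues against an even loss of endothelial cells as the whole cause, if the 20 genes are read from these cells alone. Mmrn2 rose, but in edgeR its call was lost without control 2 (adjusted p = 0.0534) or null 2 (adjusted p = 0.0639). All 10 capillary genes lay below 0, with Tcf15 (−0.68) and Rgcc (−0.75) called lower (camera p of 7.83e-07, adjusted p = 1.96e-06), and arterial genes Gja4 (−0.58) and Sema3g (−0.32) fell (camera p of 5.25e-05, adjusted p = 8.74e-05). SRF and YAP targets had a camera p of 0.00136, with Tpm2 (−0.75) lowest. With an estimated correlation the adjusted p was 0.0886 for the capillary and arterial lists and 0.153 for SRF and YAP targets. For all 3 lists another split gave as low a p, though the real split had the largest median for the capillary list (−0.499, with 0.327 in size the highest of the others) and the arterial list (−0.309, with 0.180), so capillary loss, arterial loss and lower SRF and YAP activity stay open.

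Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 801 changed genes, the real one, and the highest of the others gave 1; for called lists 4 splits gave at least the real 11, with a highest other of 13. With 10 splits the share cannot fall below 0.1. Every other split mixes control and null-labelled libraries, so a difference between them widens the spread within each side and lowers the calls. The contrast of 801 with 1 is therefore not a rate of false calls. Xist had 1798 counts in null 1 and 5738 in null 3, against 28 and 29 in control 1 and control 2. The lung surfactant gene Sftpc had 140 counts in null 2 and 0 to 10 in the others. Among the 21 lists not called, the median, mean and test differed in sign in 9.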
